A study of Mus musculus with 9 samples.

How the data were processed

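Messenger RNA was measured by sequencing in 9 libraries of B16.SIY, a mouse melanoma cell line of C57BL/6 origin that carries the model antigen SIY fused to the red fluorescent protein dsRED. Per the labels' protocols, the cells were infected with lentivirus carrying a short hairpin RNA (shRNA) and stable lines were obtained by puromycin selection. There were 3 groups of 3 libraries: a control hairpin, a first hairpin against Decr2 (shRNA1) and a second hairpin against Decr2 (shRNA2). Groups and the replicate digits 0, 1 and 2 were taken from the sample titles. The series title speaks of tumors, whereas the sample labels describe a cultured melanoma line, so the libraries are treated here as cultured cells. No label says that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

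The deposited table held 10762 genes with 1 log2 value per library, and per the file headers also the authors' fold changes, moderated t scores and p-values for each Decr2 hairpin against control. The submitters' processing notes name kallisto, FastQC and limma, without versions. The genome build, the transcript annotation, the strand setting and the filter on low genes are not given in the sources used here. The deposited log2 values of the authors behave like counts scaled to a common total: raised to the power of 2, they summed to between 969465 and 1045849 per library, and the library medians ran from 5.35 to 5.38. Genes not in the table were not analysed here and cannot be read as silent. The deposited p-values and t scores of the authors were used only to describe their own table. No column of per-library values was left without a sample.

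The table names the libraries by short codes that mark the control and the replicate digit but do not spell out which Decr2 hairpin a column belongs to. That link was read from the authors' headed comparisons in the same table. The fold changes that the authors headed as shRNA1 differed by a median of 0.000744 on the log2 scale from the difference of means assigned here to shRNA1, and 99.95% of genes lay within 0.05; against the columns assigned to shRNA2 the figure was 26.6%. The fold changes headed as shRNA2 lay within 0.05 of the columns assigned to shRNA2 in 99.7% of genes. If those headings were exchanged in the deposited table, the hairpin names would be exchanged throughout the results below.

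The number of reads per library is unknown, since the table gives no totals. Under an assumed offset of 0.5 reads, between 6.5% and 21% of the 200 lowest values of a library lay within 0.05 of a whole multiple of a common step, against about 10% for values without steps, so whole reads were not recovered. Precision is therefore given by the spread between libraries and not by counting error. Gene symbols were assigned from Ensembl gene identifiers through a reference table, which matched 10759 genes and left 3 with the deposited name. Of the deposited gene names, 17 had been turned into spreadsheet dates and were restored in this way, and 6 symbols were held by 2 identifiers each. Coordinates are those of GENCODE release M21 on assembly GRCm38, which may differ from the build of the authors.

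Differential expression was tested with limma 3.58.1 in R 4.3.3 on the log2 values as deposited, with a mean per group, all 9 libraries in the fit and an intensity trend in the variance prior (3.30 prior and 6 residual degrees of freedom). The contrasts were each Decr2 hairpin against control, the mean of both hairpins against control, and shRNA2 against shRNA1. P-values were adjusted by Benjamini and Hochberg over all genes, and a gene was called at an adjusted p under 0.05 with no fold minimum. A gene counted as called with both hairpins when it passed in both comparisons with the same sign. No filter and no pseudocount were added, since the values were already on a log2 scale. Errors of fold changes are standard errors (SE) from this fit, and intervals are 95% confidence intervals.

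Before the data were examined, 30 gene lists were fixed for peroxisomes, lipid metabolism, ferroptosis, antigen presentation, interferon, pigment, cell cycle, stress responses and related subjects, together with 74 marker genes of 8 other cell types. Lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, again with the correlation estimated for each list, and with fry; Decr2 itself was left out of its lists. The genes named were also chosen by a rule fixed beforehand. From genes with plain symbols, a mean level above the median gene and every hairpin library outside the range of the controls, the rule took the 12 risen and 12 fallen genes with the largest smaller change of the hairpins, and the 8 higher and 8 lower genes by fold change for each single contrast. From each list it took up to 4 members that passed with both hairpins by adjusted p, failing that up to 4 that passed in the average, and failing that the 2 of the highest level. Results of 1 gene that met this rule are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

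The replicate digits recur in every group, so it was checked whether libraries with the same digit deviate from their group means together. Across the 5381 genes above the median level, the correlation of deviations was between 0.183 and 0.743 for the 9 same-digit pairs. For pairs of different digits it was between -0.814 and 0.740. Over all genes these ranges were 0.126 to 0.644 and -0.629 to 0.531. Every same-digit pair was above 0.1, so by the rule fixed beforehand the digits counted as pairing the libraries. The main fit nevertheless has no term for the digit, so its counts, errors, p-values and list tests ignore this pairing. The pairing is a property of the data, since the labels do not say what the digit marks. Only 4 of the 9 libraries correlated best with libraries of their own digit, and the structure mainly parted replicate 0 from replicates 1 and 2. The fit with the digit as a block (4 residual degrees of freedom) is given beside a result where it changed a call or moved a count by more than 1.5 times.

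The fit was tested on simulated data for the same 10762 genes with 200 changed genes planted. For calls with both hairpins it recovered 32% of genes planted at a log2 change of 0.5, 78% at 1 and 98% at 2, with 0 false calls. For shRNA1 alone, 3.11% of calls were false, and for shRNA2 alone 4.82%. With the replicate block these shares were 8.59% and 2.55%. Each comes from 1 simulated draw in which both hairpin groups were built alike, so the hairpins cannot be ranked by them. With the block the share rose for shRNA1 and fell for shRNA2, in data drawn with an added effect of the digit. Calls added by the block may carry more doubt, which these draws do not settle for either hairpin. Alternatives tried were centring of each library, a filter on the lowest 25% of genes, limma without the trend or with a robust variance, the replicate block, each library left out in turn, only the groups compared, an adjusted p under 0.01 and a log2 fold minimum of 1. Settings added after seeing the data were a fit without the libraries numbered 0 and the replicate block with a loess correction of each library for GC content and transcript length. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.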

Results

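The data describe gene expression in cultured B16.SIY mouse melanoma cells in which Decr2 was knocked down by either of 2 hairpins, compared with the same line carrying a control hairpin. Decr2 encodes a 2,4-dienoyl-CoA reductase of peroxisomes that takes part in the breakdown of unsaturated fatty acids. Each group had 3 libraries, and each library gave a deposited log2 value for every gene of 1 shared table. The read depth is unknown. The mean correlation of a library to the others of its group was between 0.968 and 0.990 across genes, and correlations between groups overlapped this range (0.955 to 0.988). Replicate 0 of shRNA1 correlated at 0.966 with replicate 1 of its own group and at 0.984 with replicate 0 of shRNA2. No pair of libraries held identical values. Markers of immune, stromal, endothelial, epithelial and erythroid cells were nearly absent from the table: 5 of 74 were listed (Lck, Col1a1, Pdgfrb, Postn and Plvap), and none of these passed the test with either hairpin. Col1a1 was 1.71 higher with shRNA1 (adjusted p = 0.103), which passed with the replicate block (adjusted p = 0.0199).

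The targeted gene was examined first. Decr2 (ENSMUSG00000036775) is a protein-coding gene on the minus strand of chromosome 17, from 26081208 to 26090337 in GRCm38. Decr2 mRNA was lower in all 6 hairpin libraries than in the control libraries. Its mean log2 value was 3.92 ± 0.19 (SD, n = 3) with the control hairpin, 2.85 ± 0.34 (SD, n = 3) with shRNA1 and 1.19 ± 0.36 (SD, n = 3) with shRNA2. With shRNA1 it fell by 1.07 on the log2 scale (SE 0.23, limma adjusted p = 0.0195), which left 47.6% of the control level (95% interval 33.4% to 68.0%). With shRNA2 it fell by 2.73 (SE 0.23, adjusted p = 0.000568), which left 15.0% (95% interval 10.5% to 21.5%). The lines also differed from each other, with a log2 difference of shRNA2 over shRNA1 of -1.66 (SE 0.23, adjusted p = 0.0233). The authors' deposited table also called Decr2 lower with each hairpin, with adjusted p-values of 0.0116 and 0.00104. The call with shRNA1 was lost when control replicate 1 (adjusted p = 0.0872), control replicate 2 (0.0537) or shRNA1 replicate 1 (0.0579) was left out. The call between the lines was less firm, although its size stayed between -1.84 and -1.49. It held without control replicate 0 or shRNA1 replicate 0 and was lost without control replicate 1 (adjusted p = 0.0591) or 2 (0.0516), shRNA1 replicate 1 (0.0804) or 2 (0.12), or shRNA2 replicate 0 (0.0555), 1 (0.137) or 2 (0.0708), and with only the groups compared (0.116).

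**Figure D1:**
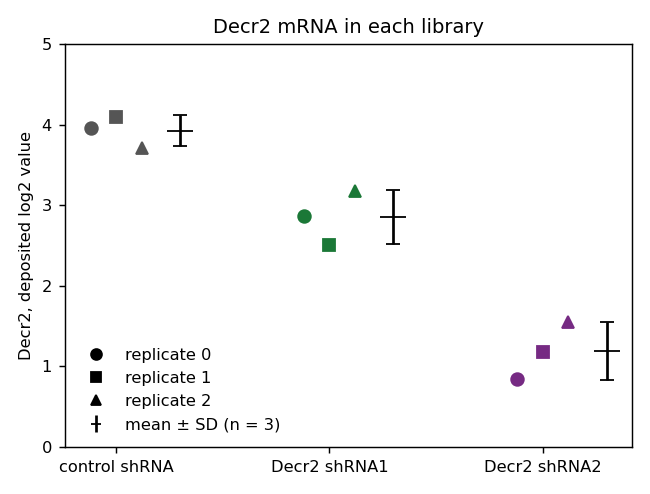
Deposited log2 value of Decr2 (y axis) in each library, by hairpin (x axis), with the replicate digit shown by the symbol and the mean ± SD of 3 libraries beside the points. The highest shRNA1 library, at 3.18, lies under the lowest control library, at 3.71, and the highest shRNA2 library lies at 1.55.

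With the first hairpin, Trib3, a pseudokinase induced by cellular stress, rose by 2.35 (SE 0.27) on the log2 scale, Chac1, which degrades glutathione, by 2.23 (SE 0.35), and Aldh1l2, a mitochondrial folate enzyme, by 1.83 (SE 0.18). Atf5, Pck2, Bcat1, Sesn2 and Psph rose by between 1.42 and 1.68. The fallen genes by the naming rule were Megf10, Snx30, Gxylt2, Mtdh, the integrin Itga4, Enc1, the cyclin Ccne2 and the transferrin receptor Tfrc, with log2 fold changes between -1.01 and -0.91. In all, 1336 genes passed with shRNA1, 745 higher and 591 lower (limma, adjusted p under 0.05; 436 higher and 526 lower with the lowest 25% of genes removed), and the median size of a called change was 0.51 on the log2 scale. All 3 shRNA1 libraries lay outside the control range in 3649 genes, or 33.9% of those tested. Chance gives 10% for exchangeable libraries, a value that takes no account of the deviations shared by digit. The authors' deposited table called 1263 genes for this comparison, of which 1253 were also called here. With the replicate block the count was 2646, with only the groups compared it was 675, and 178 calls had a log2 fold change of at least 1 in size. Leaving out 1 library gave 339 calls without control replicate 1, 328 without control replicate 2, 755 without shRNA1 replicate 1 and 648 without shRNA1 replicate 2.

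With the second hairpin Trib3 rose again, as did Chac1, which rose by 2.72 (SE 0.35), and Atf5, a stress-induced transcription factor, which rose by 1.90 (SE 0.45). Pck2, Aldh1l2, Sesn2, Ddit4 and the neutral amino acid transporter Slc1a4 rose by between 1.64 and 1.73. The chaperones Hsph1, which fell by 1.11 (SE 0.15), and Hspa5 were among the fallen genes, and Fasn, the fatty acid synthase, fell by 1.02 (SE 0.17). Mcam, Nav2, Npc1, Megf10 and Tns3 fell as well, with log2 fold changes between -1.07 and -0.99. In all, 1392 genes passed with shRNA2, 782 higher and 610 lower (487 and 560 with the lowest 25% of genes removed), with a median size of 0.50. The 3 shRNA2 libraries lay outside the control range in 4175 genes, or 38.8% of those tested, where chance gives 10% for exchangeable libraries. The authors' deposited table called 1309 genes, of which 1300 were also called here. With the replicate block the count was 2583, with only the groups compared it was 1803, and 150 calls had a log2 fold change of at least 1 in size. Leaving out 1 library gave 418 calls without control replicate 1, 406 without control replicate 2, 2450 without shRNA1 replicate 0, 432 without shRNA2 replicate 1 and 471 without shRNA2 replicate 2.

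The comparison of both hairpins with control asks which changes do not belong to a single hairpin. With each hairpin 14 of 24 integrated stress response genes and 8 of 28 interferon-stimulated genes rose, while 13 of 22 unfolded protein response genes, for the most part chaperones of the endoplasmic reticulum (ER), and 11 of 29 S phase genes fell. In the average of both hairpins these 4 lists passed camera at the preset correlation (largest adjusted p = 1.05e-08; adjusted p = 0.331 with an estimated correlation). The risen genes by the naming rule were Trib3, Chac1, Aldh1l2, Atf5, Pck2, Sesn2, Psph, Gpt2, Ddit4, Nr4a3, Atf4 and Tmed10. Atf4, the transcription factor at the centre of the integrated stress response, rose by 1.07 (SE 0.22) with shRNA1 and 1.23 (SE 0.22) with shRNA2. Tmed10, a cargo receptor between ER and Golgi, rose by 1.02 with shRNA2 (SE 0.06) and 1.03 in the average of both hairpins (SE 0.05). The fallen genes were Megf10, Hspa5, Calr, Hsph1, Rhob, Pdia4, Manf, Itpr1, Creld2, Hyou1, Sipa1l3 and Fasn, with log2 fold changes between -0.67 and -1.11. A total of 813 genes passed in the same direction with both hairpins, 489 higher and 324 lower (287 and 305 with the lowest 25% of genes removed), and 4 genes passed in opposite directions. Of the 813 genes, 88 changed by at least 1 on the log2 scale with both hairpins, and 84 of these were higher.

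The overlap was set beside 2 reference values, because both comparisons use the same control libraries. In 100 simulations of unchanged groups against shared controls, at most 1 gene was called with both hairpins. With no gene changed, hardly any call can arise, so this does not show how far shared controls raise the overlap of long lists. Independent lists of the same sizes would share 54.1 higher and 33.5 lower genes, a figure that leaves the shared controls out. Neither value is a chance level for the 813 shared calls. The simulations drew noise independently for each gene and library, whereas the real libraries deviated together by digit, so chance may range wider than the simulations show. The fold changes of the hairpins correlated across genes at r = 0.806, where the simulations gave 0.499 on average, and their covariance was 0.111 against a simulated 0.0171. Genes are not independent replicates in these correlations, and with 3 control libraries that cannot be parted into groups of 2, part of the excess may come from the shared controls. The average of both hairpins against control called 1892 genes, 1043 higher and 849 lower (627 and 772 with the lowest 25% of genes removed). With the replicate block the counts were 1659 for both hairpins and 3263 for the average, and all 813 genes were among the 1659. Leaving out 1 library lowered the count for both hairpins to 188 without control replicate 1, 189 without control replicate 2, 471 and 400 without shRNA1 replicates 1 and 2, and 313 and 329 without shRNA2 replicates 1 and 2; the average gave 616 and 631 calls without control replicates 1 and 2.

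**Figure D2:**
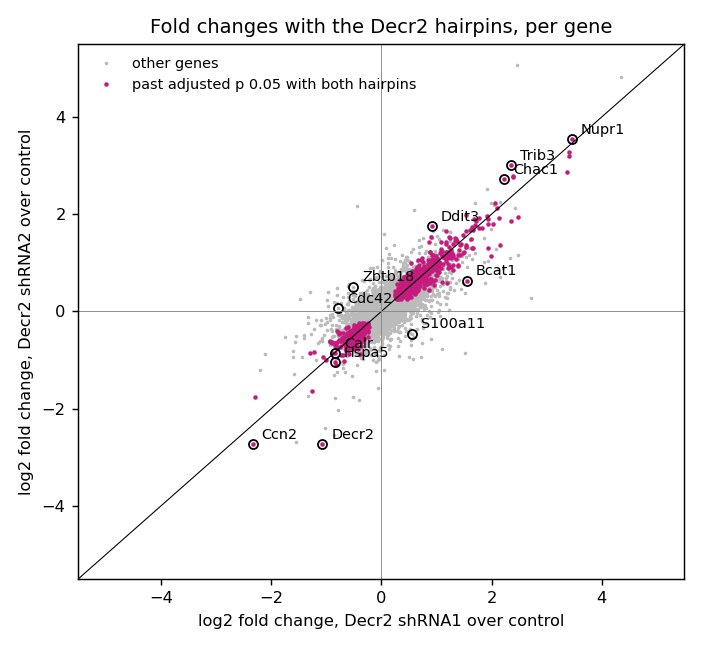
Log2 fold change of each gene over control with Decr2 shRNA1 (x axis) and Decr2 shRNA2 (y axis), with the 813 genes that passed in the same direction with both hairpins in colour, the line of equal change drawn and named genes circled. Nupr1 lies at 3.45 and 3.54, while Decr2 lies at -1.07 and -2.73, off the line.

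The list of integrated stress response genes moved most among the 30 lists. Of its 24 measured members, 18 rose in the average of both hairpins, 0 fell and 6 did not pass; 14 rose with each hairpin, and adjusted over the list alone 20 rose. Nupr1, a stress-induced chromatin protein, rose by 3.45 (SE 0.22) and 3.54 (SE 0.22) with shRNA1 and shRNA2. Ddit4, an inhibitor of mTORC1, rose by 1.17 and 1.65, and Ddit3, which encodes the transcription factor CHOP, by 0.92 and 1.75. The median member was 1.31 higher (camera adjusted p = 2.01e-14; adjusted p = 0.331 with an estimated correlation). The list mean was higher in each hairpin library than in the control of the same digit. The same list was also lower in the libraries numbered 0 than in the others across groups, with a median of -0.58. Without the 3 libraries numbered 0, a setting added after seeing the data, 24 of 24 members rose.

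The list of the unfolded protein response moved the other way. Of 22 measured members 16 fell, 1 rose and 5 did not pass, with 13 fallen with each hairpin and 16 fallen and 2 risen when adjusted over the list alone. The fallen members were for the most part ER chaperones and folding enzymes. Hspa5, the main ER chaperone, fell by 0.95 in the average (SE 0.08). With shRNA1 and shRNA2, Pdia4 fell by 0.74 and 0.89, Pdia6 by 0.60 and 0.58, and Hsp90b1 by 0.67 and 0.65. The member that rose was Herpud1, a component of ER-associated degradation, at 0.52 and 0.73; it was chosen after its value was seen. The median member was at -0.50 (camera adjusted p = 1.05e-08; adjusted p = 0.331 with an estimated correlation). Across groups the list was 0.13 higher at the median in the libraries numbered 0, and without those libraries 17 of 22 members fell. Without control replicate 1 no member rose, and without shRNA1 replicate 0, 2 did.

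Interferon-stimulated genes rose from low levels. Of 28 measured members 13 rose, 0 fell and 15 did not pass; 8 rose with each hairpin, and adjusted over the list alone 22 rose. Ifih1, a sensor of double-stranded RNA, rose by 1.47 (SE 0.21) and 1.57 (SE 0.21), Isg15 by 1.45 and 1.39 (SE 0.26 each), Ifit1 by 1.09 and 1.14, and Parp14 by 1.08 and 1.43. The median member was 0.60 higher (camera adjusted p = 1.97e-09; adjusted p = 0.331 with an estimated correlation). In the replicate block 24 of 28 members rose, without the libraries numbered 0, 22 did, and without control replicate 1 or control replicate 2 only 6 did. The list stood higher in the libraries numbered 0 across groups as well, with a median of 0.35. Related lists were less uniform: of 16 genes of MHC class I presentation 6 rose and 3 fell, and of 17 genes of interferon gamma signalling and checkpoint ligands 5 rose. H2-K1, a class I heavy chain with close paralogs, was 0.88 higher with either hairpin (SE 0.17), and Psme2, a proteasome activator subunit, was 0.70 and 0.60 higher, while Calr and Pdia3, chaperones that also belong to the unfolded protein response list, fell. Adjusted over the list alone, 8 class I genes rose and 3 fell, and 5 genes of the interferon gamma list rose. The class I list missed the threshold (camera adjusted p = 0.0546) and passed with the replicate block (0.0352; adjusted p = 0.449 with an estimated correlation). The class I list also passed without control replicate 0 (0.0382), shRNA1 replicate 1 (0.0197) or 2 (0.0388) or shRNA2 replicate 2 (0.0404), and with centred libraries (0.0497), in no case with an estimated correlation (lowest adjusted p = 0.555 with an estimated correlation), and only 3 members rose without control replicate 2. It missed fry (adjusted p = 0.112), and passed it in the blocked fit (0.0136), without shRNA1 replicate 1 (0.048) and without the libraries numbered 0 (0.0249). It stood 0.21 higher at the median in the libraries numbered 0 across groups. The interferon gamma list missed camera but passed fry, which tests the direction of a list without comparing it with other genes (adjusted p = 0.000148). In it, Socs3 rose by 0.96 and 0.54 and Stat3 by 0.91 and 1.08. Without control replicate 1 or 2 only 2 of its genes rose, without shRNA1 replicate 2 or shRNA2 replicate 2 only 3 did, and in the blocked fit 6 rose and 1 fell.

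Replication genes fell by small amounts. Of 29 measured S phase genes 14 fell, 0 rose and 15 did not pass, 11 fell with each hairpin, and adjusted over the list alone 20 fell. Cdc6, a licensing factor of replication origins, fell by 0.84 (SE 0.07) and 0.66 (SE 0.07), Tyms by 0.49 and 0.50, Mcm5 by 0.37 and 0.38, and Rrm2 by 0.40 and 0.38. The median member was at -0.31 (camera adjusted p = 1.97e-09; adjusted p = 0.331 with an estimated correlation), and without the libraries numbered 0, 21 of 29 fell, while without control replicate 1 or control replicate 2, 8 fell. The S phase list was also lower in the libraries numbered 0 across groups, with a median of -0.08. Of 30 G2 and M phase genes 3 fell (Kif23, Ttk and Bub1b) and the median was -0.17 (camera adjusted p = 0.00221; adjusted p = 0.331 with an estimated correlation); in the replicate block 11 fell and 1 rose, and adjusted over the list alone 0 did. With 1 library left out, the number of fallen G2 and M phase genes ran from 0 to 7. It was 0 without control replicate 1 or 2, among others, and 7 without shRNA1 replicate 0. With centred libraries 6 G2 and M phase genes fell.

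**Figure D3:**
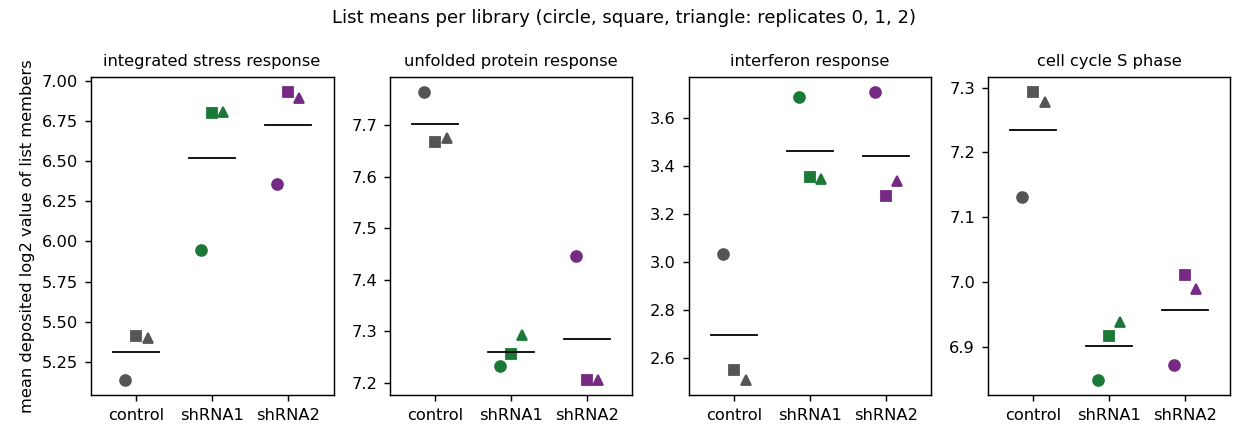
Mean deposited log2 value over the members of 4 gene lists (y axis, a separate range in each panel) in each library, by hairpin (x axis), with the replicate digit shown by the symbol and group means as lines. The median difference of stress response genes from the control of the same digit ran from 0.67 to 1.49 over the 6 hairpin libraries, and that of unfolded protein response genes from -0.63 to -0.41.

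Decr2 belongs to the list of peroxisomal fatty acid oxidation. Of 17 other genes of this list 2 rose in the average (Pecr by 0.49, SE 0.11, and Ech1 by 0.34, SE 0.10) and 0 fell, with a median of 0.29 (camera adjusted p = 0.0274; adjusted p = 0.614 with an estimated correlation), and adjusted over the list alone 4 rose. It missed the threshold with fry (adjusted p = 0.0587), which the other lists called by camera in the average passed (0.00838 or below). It passed fry in the blocked fit (0.0132), without control replicate 0 (0.0478), without shRNA1 replicate 0 (0.0401) and without the libraries numbered 0 (0.00167). The list stood 0.20 higher at the median in the libraries numbered 0 across groups. The blocked fit called 8 of these 17 genes, and the fit with centred libraries called 1. None passed without control replicate 1 or 2, 1 did without shRNA1 replicate 2, shRNA2 replicate 0 or shRNA2 replicate 1, and 4 did without shRNA1 replicate 0, and the list missed the threshold without control replicate 1 (adjusted p = 0.0521), without shRNA1 replicate 0 (0.0946) and without the libraries numbered 0 (0.0545). Of 20 genes of peroxisome assembly 4 rose, among them the membrane protein Pxmp4 by 0.71 and 0.82 and the import receptor Pex7 by 0.49 and 0.53 (camera adjusted p = 0.0162; adjusted p = 0.331 with an estimated correlation). Adjusted over the list alone 4 assembly genes rose, and 2 rose without control replicate 1 or control replicate 2. Of 21 genes of mitochondrial fatty acid oxidation 3 rose (Slc22a5, Acadl and Cpt1c) and the list did not pass (camera adjusted p = 0.376). None of 10 ether lipid genes passed, with Agps at -0.24 and -0.06 and Agpat3 at 0.15 and 0.19. Adjusted over the list alone, 3 mitochondrial and 0 ether lipid genes rose. The blocked fit called 1 ether lipid gene higher and, of the mitochondrial list, 4 genes higher and 1 lower, and without control replicate 1 or 2 none of the mitochondrial list passed. Without shRNA1 replicate 0, 1 ether lipid gene and 2 mitochondrial genes fell, and without shRNA2 replicate 0, 1 mitochondrial gene fell. The mitochondrial list stood 0.12 higher at the median in the libraries numbered 0.

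Ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, is among the processes that the knockdown of a fatty acid enzyme could concern. Of 20 ferroptosis drivers 3 rose and 2 fell, and of 27 suppressors 6 rose and 1 fell. Tfrc, the iron importer, fell by 0.91 and 0.64, while Slc40a1, the iron exporter, rose by 0.45 and 0.50 and Slc3a2, a subunit of the cystine transporter, by 0.69 and 0.83. Scd1, a desaturase that makes monounsaturated fatty acids, rose by 0.86 and 0.44. Neither list passed camera (adjusted p = 0.998 for drivers and 0.196 for suppressors), while the suppressors, higher on balance, passed fry (adjusted p = 0.00232) and the drivers did not (0.288; 0.015 without shRNA2 replicate 0 and 0.000191 without the libraries numbered 0). Fatty acid synthesis missed fry (0.255) and passed it in the blocked fit (0.0487) and without control replicate 0 (0.0478). Without the libraries numbered 0, fry also passed NRF2 targets (0.023), cholesterol synthesis (0.00773) and iron handling (0.0192). Chac1 and Slc3a2 also belong to the stress response list. Fatty acid synthesis genes went both ways, with 5 of 18 higher (Acss2 at 0.58 and 0.77, and Acacb at 0.80 and 0.84, among them) and 3 lower, and the list did not pass (0.819). Of 27 genes of phospholipid remodelling 2 rose, Lpcat2 among them at 0.89 and 0.85, and 2 fell, Agpat5 and Lpcat1 (0.938 for the list). Cholesterol synthesis had 3 risen genes of 24 (Pmvk and Tm7sf2 among them; 0.172), iron handling 4 risen and 2 fallen of 22 (0.938), and NRF2 targets 8 risen, Gstm2 among them, and 2 fallen of 27 (0.859). Median and mean differed in sign for drivers (-0.01 and 0.08), NRF2 targets (-0.03 and 0.17), fatty acid synthesis (-0.01 and 0.06) and iron handling (-0.05 and 0.02). For iron handling the direction was down in camera and up in fry, and for the other 3 lists it was up in both. Adjusted over the list alone, 6 fatty acid synthesis genes fell and 2 cholesterol genes rose, and the other counts of this paragraph stayed the same. In the blocked fit 7 cholesterol genes rose and 2 fell, 4 phospholipid genes rose and 4 fell, 5 fatty acid synthesis genes fell, 5 iron genes fell, and 4 NRF2 targets and 2 suppressors fell. The risen genes depended on single control libraries: without control replicate 1 or 2, 0 NRF2 targets, 0 cholesterol genes, 1 ferroptosis driver, 3 suppressors, 3 fatty acid synthesis genes and 1 iron gene rose, and 1 NRF2 target, 1 fatty acid synthesis gene and 0 suppressors fell. The fallen drivers and iron genes were then 0 each without control replicate 1 and 1 each without control replicate 2. Without control replicate 0, 5 NRF2 targets and 1 cholesterol gene rose and 1 fatty acid synthesis gene fell. Without shRNA1 replicate 0, 4 drivers, 4 NRF2 targets, 4 iron genes and 1 cholesterol gene fell, and without shRNA1 replicate 1 or 2, 1 NRF2 target fell. Without shRNA2 replicate 1, 1 cholesterol gene rose and 1 driver and 1 NRF2 target fell, and without shRNA2 replicate 2, 1 driver, 1 NRF2 target, 1 iron gene and 0 suppressors fell. Of the NRF2 targets 7 rose with shRNA1 and 1 with shRNA2. The cholesterol list passed without control replicate 0 (camera adjusted p = 0.0227; adjusted p = 0.547 with an estimated correlation). It also passed without the libraries numbered 0, where 13 of its 24 genes rose and 2 fell (0.0191; adjusted p = 0.477 with an estimated correlation). Across groups the libraries numbered 0 stood 0.17 higher at the median in the cholesterol list and 0.14 higher in that of phospholipid remodelling.

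The remaining lists did not pass camera in the average contrast. With fry, p53 targets (higher, adjusted p = 0.0178), cytokines (higher, 0.0166) and the dedifferentiated state (lower, 0.00838) passed. Cytokines missed fry without control replicate 2 (0.0688) and the dedifferentiated state without the libraries numbered 0 (0.0713). Hypoxia targets passed fry without control replicate 0 (0.0153). Without the libraries numbered 0 fry passed hypoxia targets (0.00465), pigment (8.98e-05), glycolysis (0.00296) and immediate early genes (0.0168). The p53 list passed with shRNA1 alone (camera adjusted p = 0.0296; adjusted p = 0.468 with an estimated correlation). Of 19 p53 targets 5 rose and 1 fell (camera adjusted p = 0.066, and 0.0352 with the replicate block, or 0.48 with an estimated correlation). Trp53inp1 was at 0.81 and 0.58, Gadd45a at 1.61 and 1.68 and Cdkn1a at 0.58 and 0.59. Sesn2, a p53 target that also rose with each hairpin, belongs to the stress response list as well. Of 22 pigment and melanocyte genes only Pax3 passed, at -0.44 with shRNA1 and -0.16 with shRNA2 (0.179; 0.0456 with the replicate block, or 0.855 with an estimated correlation). Ccn2, a secreted matricellular protein, fell by 2.34 and 2.73 (SE 0.21 each) in a list of the dedifferentiated melanoma state in which 2 of 18 genes fell (0.243). The mean log2 value of Ccn2 was low, at 1.49 against 5.35 for the median gene. In the extracellular matrix list Timp3 rose, Lamb1 fell by 1.27 and 1.64, and 5 of 17 genes passed (0.458). Ccl5, a chemokine near the lower end of expression, rose by 1.93 and 1.81 (SE 0.43 each) and Nfkbia by 0.77 and 0.78 in the list of cytokines, of which 3 of 8 rose and 1 fell (0.376). Vegfa rose by 0.83 and 0.85 and Ak4 fell among 19 hypoxia targets (0.437). Slc2a1 was the only glycolysis gene of 23 to pass, at -0.43 and -0.41 (0.179). Of 24 genes of cell death 3 rose and 3 fell in the average (0.938), and Gsdme fell by 0.41 with either hairpin. The median of the cell death list was 0.04 and the mean 0.02, with the direction down in camera and fry. Without control replicate 1 or 2, 0 cell death genes rose. Of 13 mitochondrially encoded genes 2 rose, mt-Nd4l among them (0.0896), of 33 nuclear genes of oxidative phosphorylation 2 fell, Atp5a1 and Sdhd (0.938), and of 32 ribosomal protein genes none passed in the average, with Rplp0 and Rps2 within 0.08 of control with each hairpin (0.725). The list of immediate early genes had 1 risen and 1 fallen member of 17 (0.114; 0.0456 with the replicate block, or 0.616 with an estimated correlation), and that of interferon gamma signalling missed the threshold at 0.107. Adjusted over the list alone, the counts became 6 risen p53 targets, 5 risen hypoxia targets, 3 risen mitochondrially encoded genes, 3 risen and 2 fallen immediate early genes and 0 fallen genes of oxidative phosphorylation, and the others stayed the same. With the replicate block 8 p53 targets and 7 immediate early genes rose, 2 immediate early genes, 6 pigment genes, 4 genes of the dedifferentiated state and 2 cytokines fell, 3 matrix genes rose, and 3 glycolysis genes rose and 7 fell. Pigment genes stood 0.60 higher at the median, glycolysis genes 0.24 and oxidative phosphorylation genes 0.13 higher in the libraries numbered 0 across groups. Without those libraries 16 of 22 pigment genes fell (camera adjusted p = 1.19e-07; adjusted p = 0.0838 with an estimated correlation), and 14 of 23 glycolysis genes fell and 5 rose (0.00923; adjusted p = 0.258 with an estimated correlation). Leaving out 1 library also brought lists past the threshold: pigment genes without shRNA1 replicate 0 (0.0421) or shRNA2 replicate 0 (0.00261), glycolysis without shRNA2 replicate 0 (0.0178), p53 targets without control replicate 1 (0.0255), control replicate 2 (0.0203) or shRNA2 replicate 0 (0.0291), immediate early genes without control replicate 1 (0.0303) or shRNA2 replicate 0 (0.0464), and mitochondrially encoded genes without shRNA1 replicate 1 (0.00553) or shRNA2 replicate 0 (0.0161). None of these 5 lists passed in the fits just named when the correlation was estimated (lowest adjusted p = 0.403 with an estimated correlation). The small counts of these lists also moved with single libraries. Without control replicate 1 or 2, 1 cytokine rose and 0 fell, 1 gene of the dedifferentiated state fell, 0 mitochondrially encoded genes rose, and 0 genes of oxidative phosphorylation, 0 p53 targets, 0 pigment and 0 glycolysis genes fell. The fallen matrix genes were 0 without control replicate 1 and 1 without control replicate 2. Without control replicate 0, 3 matrix genes rose and 2 fell, 1 gene of the dedifferentiated state rose and 1 fell, 2 p53 targets and 1 gene of oxidative phosphorylation fell, and 0 glycolysis genes did. Without shRNA1 replicate 0, 3 immediate early genes, 2 matrix genes and 2 genes of the dedifferentiated state rose, 3 glycolysis genes rose and 3 fell, and 2 pigment genes, 2 cytokines and 2 ribosomal protein genes fell. Without shRNA1 replicate 1, 4 mitochondrially encoded and 2 immediate early genes rose, and 1 gene each of the dedifferentiated state and oxidative phosphorylation fell. Without shRNA2 replicate 0, 5 immediate early genes rose and 4 pigment and 2 glycolysis genes fell. Without shRNA1 replicate 2, shRNA2 replicate 1 or shRNA2 replicate 2, 1 mitochondrially encoded gene rose and 1 gene of oxidative phosphorylation fell. Without shRNA2 replicate 1 or 2 no p53 target fell, and without shRNA2 replicate 1, 1 gene of the dedifferentiated state fell.

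**Figure D4:**
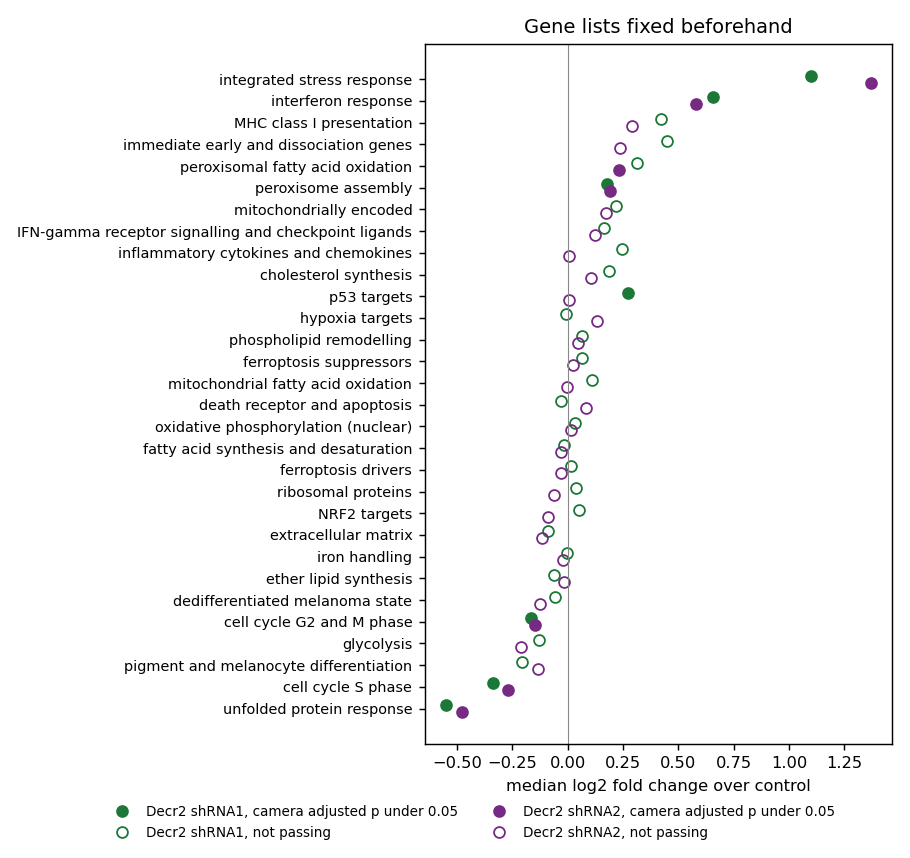
Median log2 fold change over control (x axis) of the measured members of each of 30 gene lists (y axis) with Decr2 shRNA1 and Decr2 shRNA2, filled where camera at the preset correlation passed an adjusted p of 0.05. The integrated stress response stands highest and the unfolded protein response lowest with both hairpins.

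The last comparison asks where the lines with different Decr2 hairpins differed from each other. Decr2 was among the genes that did. Cdc42 was 0.86 higher with shRNA2 (SE 0.06, adjusted p = 0.00118), after a fall of 0.79 with shRNA1 and a fold change of 0.06 with shRNA2 against control. Me1, the cytosolic malic enzyme, was lower with shRNA2 at -0.78 (SE 0.09, adjusted p = 0.0121), and Npc1, a lysosomal cholesterol transporter, at -0.84 (SE 0.13, adjusted p = 0.0377). Ddit3 was 0.83 higher with shRNA2 (SE 0.10, adjusted p = 0.0167). Also higher with shRNA2 were Zbtb18, Dpysl3, Idh1, Fstl1, Mcoln3, Cdkn2d and Gnai3, and also lower were S100a11, Tns3, Bcat1, Cluh, Dgcr2 and Fut8. In all 49 genes differed, 24 higher and 25 lower with shRNA2. Libraries of the lines did not overlap in 1550 genes, or 14.4% of those tested. Chance gives 10% for exchangeable libraries, which leaves the deviations shared by digit out of account. Among the lists, NRF2 targets were lower with shRNA2 (median -0.17, camera adjusted p = 9.02e-06; adjusted p = 0.584 with an estimated correlation), as were ribosomal proteins (median -0.10, camera adjusted p = 0.000489; adjusted p = 0.92 with an estimated correlation) and fatty acid synthesis (median -0.08, camera adjusted p = 0.0184; adjusted p = 0.92 with an estimated correlation), and stress response genes were higher (median 0.15, camera adjusted p = 0.0223; adjusted p = 0.92 with an estimated correlation). None of these 4 lists passed fry (lowest adjusted p = 0.134). Cdc42 kept its call with each of the 9 libraries left out, and the other named genes lost theirs in 4 to 8 of those fits. In the blocked fit 201 genes differed, with only the groups compared 6 did, and with 1 library left out it was 15 and 13 without control replicates 1 and 2, 94, 3 and 4 without shRNA1 replicates 0, 1 and 2, and 17, 4 and 3 without shRNA2 replicates 0, 1 and 2.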

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

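The tests of a proportional response, of the shared control libraries, of a batch of the libraries numbered 0 and of the state of those libraries were chosen after their results were seen, as were the fit without those libraries, the splits that part every replicate digit and the list of cytosolic tRNA synthetases, of which 1 symbol was also corrected after a first look.

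The lines with different Decr2 hairpins differed in 49 genes by a direct test of shRNA2 against shRNA1. Decr2 itself differed by -1.66 on the log2 scale, a call that was lost in 7 of 9 fits with 1 library left out. Among the named genes, Zbtb18 (1.02), Dpysl3 (0.88), Cdc42 (0.86), Ddit3 (0.83), Idh1 (0.68), Fstl1 (0.63), Mcoln3 (0.57), Cdkn2d (0.55) and Gnai3 (0.50) were higher with shRNA2. Fut8 (-0.52), Dgcr2 (-0.56), Cluh (-0.62), Me1 (-0.78), Npc1 (-0.84), Bcat1 (-0.92), Tns3 (-0.94) and S100a11 (-1.02) were lower. Of the gene lists, NRF2 targets (median -0.17), fatty acid synthesis (-0.0801), ribosomal proteins (-0.10) and the integrated stress response (0.15) differed in the camera test, and none of these passed with an estimated correlation. Single libraries far from their group were not searched for, since groups of 3 are too small.

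The hairpins moved genes by similar amounts although Decr2 mRNA differed between the lines. The shRNA2 and shRNA1 log2 fold changes were compared over the 1891 genes other than Decr2 called in the average. Their main axis through the origin, which treats both hairpins alike and is not a regression line, had a slope of 0.976. This slope was at most 1.06 with 1 library left out, whereas the log2 fold change of Decr2 was 2.55 times as large with shRNA2. These slopes argue only against a response in proportion to the log2 change of Decr2. As shares of control, 47.6% and 15.0% of Decr2 mRNA were left, and a response in proportion to the share lost was not tested. The genes were also chosen by the average of both hairpins, which can draw the slope toward equal change. The covariance of the fold changes was 0.111, against at most 0.0215 in 100 simulations of the shared control libraries. This argues against independent noise of the shared controls as the whole source. The simulations lack the deviations that real libraries share by digit, so they do not exclude chance values of that kind. A difference of the single control line cannot be told apart, because the design holds 1 control line and every comparison uses it. Effects that set in at the weaker loss of Decr2, and off-target effects shared by the hairpin lines, could not be tested.

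The libraries numbered 0 deviated together in all groups, with a lowest correlation of deviations of 0.387 over all genes (0.517 over the genes above the median level). A shared culture or library batch predicts such values, but so does any cause shared by these libraries, so the values do not tell causes apart. In a fit with a term for these libraries, which draws on the same deviations, 3239 genes passed, 1640 higher and 1599 lower. After correction for GC content and transcript length the lowest correlation over all genes was 0.373, which argues against these as the whole cause. The labels do not say what the digit marks, and no biological explanation was tested, since the design gives none.

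Integrated stress response genes rose while endoplasmic reticulum chaperones fell. With the replicate block, correction for GC content and transcript length left the median of the stress response genes at 1.30 (1.31 before) and of the unfolded protein response genes at -0.51 (-0.50 before), which argues against both as the cause. A shift along the state in which libraries numbered 0 differ from the others would need a pigment list median near -1.36, and it was -0.20 (quartiles -0.29 and 0.02). Whether a wider set of ATF4-responsive genes moved stays open. Cytosolic tRNA synthetases had a median of 0.23, with 3 of 20 risen (Cars, Sars and Tars) and 3 fallen (Hars, Kars and Rars). The list was not parted by whether a member responds to ATF4, so its median cannot decide this. A biological response to the Decr2 hairpins stays possible but untested against the single control line.

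Other splits of the libraries were counted for each number of called genes. For shRNA1, shRNA2 and the hairpin lines against each other, 1 of 10 splits, the real one, gave as many calls (1336, 1392 and 49, against at most 1 in any other split), and 10 splits cannot give a share under 0.1. For both hairpins and for the average, 1 of 100 drawn splits (of 840 possible) gave as many, which argues against chance in the grouping of the libraries. The highest other splits gave 751 and 1864 calls, and these kept the 3 control libraries in 1 group; splits that parted the controls gave at most 186 and 847. Of the 108 splits that part every replicate digit as the real one does, 100 were drawn, and 1 of these, the real one, gave as many calls for both hairpins and for the average, with 577 and 1502 as the highest others, which kept the 3 control libraries in 1 group (at most 4 and 18 where these were parted).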

How the results depend on the processing

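The fits without the libraries numbered 0 and with the replicate block plus correction for GC content and transcript length were chosen after the data were seen. No call of a named gene and no Decr2 fold change reversed its direction under the settings run. The count of calls depended strongly on the threshold, the block and the control libraries. A stricter threshold lowers a count by construction, whereas leaving out libraries moved counts both ways, and the cause was not tested. For shRNA1, shRNA2, both hairpins, the average and the hairpin difference in turn, the replicate block gave 2646, 2583, 1659, 3263 and 201 calls against 1336, 1392, 813, 1892 and 49. An adjusted p under 0.01 gave 276, 302, 151, 582 and 3, a log2 fold change of at least 1 gave 178, 150, 88, 166 and 12, the fit without the libraries numbered 0 gave 3711, 4011, 2547, 4452 and 955, and the block with GC and length correction gave 3428, 3501, 2311, 4146 and 444. With only the groups compared, shRNA1, shRNA2, both hairpins and the difference gave 675, 1803, 480 and 6. Leaving out 1 library gave 328 to 1579, 406 to 2450, 188 to 1062, 616 to 2642 and 3 to 94. Of the gene lists, 7 passed camera in the average, 0 with an estimated correlation, 11 with the block and 7 to 12 with 1 library left out (12 without shRNA2 replicate 0). Decr2 with shRNA1 stayed at -1.07 (adjusted p = 0.0195) and so missed a threshold of 0.01; leaving out 1 library gave -1.23 to -0.90, and its call was lost in 3 of those 9 fits. Decr2 with shRNA2 kept its call throughout. Between the lines Decr2 stayed between -1.84 and -1.48, and its call was lost in 7 of 9 fits with 1 library left out, with only the groups compared and at an adjusted p under 0.01. Of 192 calls of named genes, 192 held with the block, 161 of 165 tested with the lowest 25% of genes removed, 83 at an adjusted p under 0.01, 54 at the fold minimum, and 108 were lost when at least 1 of the 9 libraries was left out. With shRNA1 alone the block brought 5 further lists under the threshold: peroxisomal fatty acid oxidation (0.0398), cholesterol synthesis (0.0338), class I presentation (0.0377), pigment genes (0.0417) and immediate early genes (0.0338). With an estimated correlation these 5 did not pass (adjusted p = 0.389 to 0.825 with an estimated correlation). It ended no call of a named gene, and apart from these values and those printed beside the results it changed no other camera or fry call of a list in the average. The higher share of calls was 55.8% for shRNA1, 56.2% for shRNA2, 60.1% for both hairpins and 55.1% for the average. Centring lowered it to 50.8%, 51.2%, 54.4% and 50.6%, close to an even split except for both hairpins. Removing the lowest 25% of genes turned the majority from higher to lower, at 45.3%, 46.5%, 48.5% and 44.8%. Small medians of lists that did not pass camera in the average also changed sign without the libraries numbered 0. Oxidative phosphorylation went from 0.03 to -0.05, and p53 targets, which had passed fry as higher, from 0.10 to -0.01. Tests on counts and other pseudocounts were not run, since only log2 values were deposited, and with unknown depth the power for low genes is unknown.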

Other observations

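The additional gene lists, the term for the libraries numbered 0 and the genes named in this part were chosen after the data were seen.

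Genes of ribosomal RNA processing were lower with both hairpins, whereas none of 32 ribosomal protein genes passed in the average. Of 30 genes of ribosomal RNA processing and transcription 19 fell in the average and 14 fell with each hairpin. Nolc1, a nucleolar chaperone, fell by 0.72, Polr1b, a subunit of RNA polymerase I, by 0.69, Nop2, a ribosomal RNA methyltransferase, by 0.59, and Ncl, which encodes nucleolin, by 0.57. All 30 members were lower, with a median of -0.44 (camera adjusted p = 1.34e-15; adjusted p = 0.0612 with an estimated correlation). With shRNA2 alone the median was -0.48 (adjusted p = 0.047 with an estimated correlation) and with shRNA1 alone -0.37 (adjusted p = 0.0999 with an estimated correlation). Between the lines the list was lower with shRNA2, with a median of -0.13 and no member called. There camera gave an adjusted p of 0.000144, and 0.302 with an estimated correlation. Of 18 cytosolic and mitochondrial chaperones 7 fell, among them Hsph1 by 0.97 and Hspa8 by 0.57, with a median of -0.25 (camera adjusted p = 0.000306; adjusted p = 0.32 with an estimated correlation). Lists of cytosolic tRNA synthetases (3 of 20 rose and 3 fell, camera adjusted p = 0.761), mitochondrial tRNA synthetases (1 of 17 rose and 1 fell, adjusted p = 0.992) and YAP and TAZ targets (2 of 17 rose and 1 fell, adjusted p = 0.992) did not pass. The fallen YAP and TAZ target was Ccn2, at -2.54 in the average and with a low mean log2 value of 1.49.

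The libraries numbered 0 differed from the others in melanocyte genes. Of 22 pigment genes 18 were higher in these libraries across groups, with a median of 0.60 (camera adjusted p = 2.22e-10; adjusted p = 0.419 with an estimated correlation), while 19 of 24 integrated stress response genes were lower, with a median of -0.58 (camera adjusted p = 1.55e-09; adjusted p = 0.419 with an estimated correlation). Mc1r, the melanocortin receptor, was 1.10 higher (SE 0.09), S100b 1.48 higher (SE 0.09) and the metallothionein Mt2 2.43 higher (SE 0.17). Asns, the asparagine synthetase, was at -1.02 (SE 0.06), Ccn1 at -1.46 (SE 0.11) and Itgb8 at -1.88 (SE 0.15). Of 23 glycolysis genes 12 were higher (camera adjusted p = 0.000209; adjusted p = 0.419 with an estimated correlation).

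Slc7a11, the cystine transporter, was 2.15 and 2.24 higher with shRNA1 and shRNA2 but missed the threshold in each (adjusted p = 0.06 and 0.0507), and passed in the average (2.19, adjusted p = 0.0269) and with the replicate block (adjusted p = 0.000713 and 0.000741). Gpx4, which detoxifies lipid peroxides, was 0.34 higher in the average (adjusted p = 0.192, and 0.0269 with the replicate block), and Acsl4, which activates polyunsaturated fatty acids, 0.09 higher (adjusted p = 0.478). Besides Zbtb18 and S100a11, Gm14698 (-0.32 and 0.62) and Kdelc2 (0.58 and -0.54) passed in opposite directions with shRNA1 and shRNA2.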
